A study of Salmo salar with 40 samples.

How the data were processed

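Liver messenger RNA of 40 Atlantic salmon was measured, 10 fish in each of 4 groups given by the labels: control and exposed fish at day 8, and control and exposed fish at day 14. Per the labels' protocols, RNA was purified with poly-T beads, libraries were made with NEBNext reagents, and the RNA integrity number was 9.5 ± 0.2 over the 40 livers. Each library is a different fish, and the replicate numbers shared between groups do not pair fish. Which fish shared a tank, what they were fed and at what time of day they were sampled are not given in the sources used here, so the p-values measure the spread between these fish, and any difference between tanks would be part of the group differences.

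The authors deposited raw read counts per gene, as whole numbers, for 79140 gene entries and 40 fish, with no normalization. The submitters' processing notes name HISAT2, Cufflinks, HTSeq and DESeq2 without version or role. The genome build, the annotation and whether counting used the strand are not given in the sources used here. Of the gene entries, 29369 had no counts in any fish, 47181 carried LOC identifiers and 23654 were transfer RNA genes, which held at most 0.000807% of the counts of a fish. A further 5 entries had names turned into dates by a spreadsheet; they were kept in the tests and are not named. Gene names came from the deposited table and from the reference table of the assembly Ssal_v3.1, in which 39384 identifiers matched; no coordinates are given, since the authors' build is unknown. Salmon carries many duplicated genes, and how reads shared between near-identical copies, overlapping genes or antisense partners were assigned is unknown, so values of single members of gene families, such as ribosomal proteins, heat shock proteins and hepcidins, are uncertain.

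Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3, with the package data.table, version 1.17.8. Genes were kept by edgeR's filterByExpr with a minimum count of 10 and a minimum total of 15, which left 30397 genes with 99.9% of all counts. Libraries were scaled with TMM. A robust quasi-likelihood model with 1 mean per group was fitted over all 40 fish, and 5 contrasts were tested: lufenuron at each day, the difference of these effects, and the change from day 8 to day 14 in controls and in exposed fish. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The common biological coefficient of variation was 0.371. Values in CPM, the usual scaling of counts by library size, use the TMM-scaled library sizes. The deposited counts sum to 43.4 M to 76.8 M per fish, a depth at which 1 CPM is at least 41.8 reads, so that counting error is small beside the spread between fish for genes at that level.

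The 30 gene lists, the test, the contrasts of the lists with lufenuron, the alternatives and the rule for naming genes were fixed before the data were examined, except where the text says that a choice was made after the data were seen. A gene joined a list by its symbol, with the suffixes of duplicated genes, or by its full name. Names were compared up to their first comma, which put tnfaip1 into the acute phase list although it is named only as induced by tumor necrosis factor; shortened names shared by different genes were excepted, and the symbols catb, cdc20b and bub1b were left out as other genes. Because each duplicate counts as a member, large families weigh more in a list. Lists were tested with camera, which compares a list with all other genes at a preset correlation of 0.01, and with an estimated correlation and fry as alternatives, adjusted over the 30 lists within a contrast. Counts adjusted over the list alone are given beside those over all genes.

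Named genes at day 8 are the 10 largest rises and the 10 largest falls among named genes with an adjusted p under 0.05, a mean of at least 1 CPM over the 20 fish of the day and at least 8 of the 10 exposed fish beyond the control median. Where none passed, as at day 14, the 5 genes with the smallest p in each direction are given as values. For the difference between days and each change over time, the 5 largest in each direction are named, except for 1 gene of the difference that, like 1 gene of the SUMO list, is not reported here. Of each list, up to 4 members past the threshold are named, or up to 2 where none passed, and any member of the SUMO list may be named. Other genes that are singled out were chosen after their values were seen and stand in the closing observations.

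Body weight, condition factor and total counts were compared within each day by two-sided permutation tests of the mean difference with 100000 resamples, or by an exact test for groups under 10. Principal components used log2 CPM with a prior count of 2 over the 5000 most variable genes. Duplicate libraries were looked for with a chi-square per gene over genes with a mean count of at least 50. Alternatives were RLE size factors, total counts as the only scaling, no filter on low counts, DESeq2 1.42.0, only the groups compared, the replicate number as a block, body weight as a covariate, non-robust quasi-likelihood, the fit without day 14 controls under 20 g, and each fish left out. Alternatives added after the data were seen were the fit without the fish whose exocrine pancreas markers sum to over 50 CPM, the log2 sum of these markers as a covariate, every library thinned to the smallest total, and list tests over time. Lists of 46 measured fasting-induced and 42 measured glucocorticoid-induced genes, and 9 gene families chosen by name, were also added then. Figures were drawn with matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.

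The gene tests were tested on simulated data, with counts drawn for 30073 genes from the means and library sizes of these fish. With 100 genes changed 1.5-fold and 100 changed 2-fold at a simulated day 8, edgeR called 31 and 67 of them, with 6 false calls of 104 (5.77%), and DESeq2 called 39 and 73, with 17 false calls of 129 (13.2%). A simulated list of 27 lowered genes had an adjusted p of 5.71e-45 in camera, and 0 of 30 unchanged lists were called. The genes were drawn independently of each other, so the simulation does not show how the list test behaves with correlated genes. In other splits of the real fish at day 8, up to 19 of the 30 gene lists passed camera.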

Results

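The liver transcriptome was measured by poly-A RNA sequencing in 40 Atlantic salmon, with 1 library per fish. Lufenuron is a benzoylurea that blocks chitin synthesis in arthropods and is used against sea lice, the crustacean parasites of farmed salmon. Exposed fish received 5 mg of lufenuron per kg, and controls received none. Livers of 10 control and 10 exposed fish were collected at day 8, 1 day after treatment had ended, and livers of 10 further fish of each kind at day 14, 7 days after it had ended. The question posed by the series is whether exposure lowers gene expression in the liver, including the pathway that attaches the small protein SUMO to other proteins, and whether such a change passes.

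Between 43.4 M and 76.8 M (mega) reads per fish were assigned to genes, with a median of 56.7 M, and 35996 to 39403 genes had at least 1 read. The 10 most abundant genes took 17.6% to 24.9% of the reads of a fish. None of the 780 pairs of libraries agreed within sampling noise over 22080 genes (smallest chi-square per gene 50.4, median within a group 155), so each library was counted as 1 fish. The first principal component held 18.6% of the variance of the 5000 most variable genes and followed the sampling day. Its mean was -21.4 ± 13.5 in day 8 controls, -45.5 ± 14.7 in day 8 exposed fish, 37.6 ± 14.0 in day 14 controls and 29.3 ± 18.7 in day 14 exposed fish (SD, n = 10 each).

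**Figure D1:**
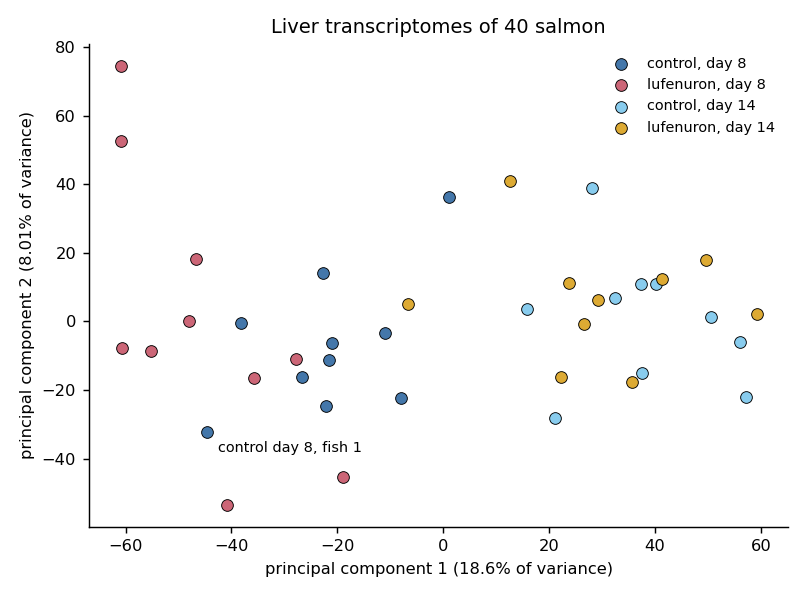
Positions of the 40 fish on the first and second principal components of log2 CPM over 5000 genes, 1 point per fish and 1 colour per group; the axes give the share of variance of each component, 18.6% and 8.01%. Day 8 fish lie mostly on the negative side of the first component and day 14 fish on the positive side.

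Body size and sequencing depth were compared between exposed and control fish within each day by two-sided permutation tests with 100000 resamples. At day 8 the exposed fish weighed 36.7 ± 3.0 g and the controls 37.6 ± 2.5 g (SD, n = 10, p = 0.526, adjusted over the 3 measures 0.789). At day 14 the weights were 45.1 ± 10.8 g and 39.1 ± 16.5 g (p = 0.356, adjusted 0.477), and the condition factor, 100 times weight over the cube of length, was 1.06 ± 0.035 against 0.925 ± 0.266 (p = 0.127, adjusted 0.380). Day 14 control fish 6, 7 and 10 weighed 18, 18 and 17 g. Fish 7 and 10 were 16.5 and 15.4 cm long, with condition factors of 0.401 and 0.465, while control fish 5 weighed 46 g at 15.9 cm. Whether these 2 recorded weights are right is not known, so the day 14 weights, the condition factor and the fit with body weight as a covariate are uncertain. Without the 3 light fish the weight difference turned to -3.19 g (exact permutation p = 0.534). The condition factor was then 1.06 ± 0.035 in exposed fish (n = 10) and 1.05 ± 0.067 in controls (SD, n = 7, exact permutation p = 0.495). Assigned reads were 52.1 ± 4.5 M in exposed and 57.96 ± 10.05 M in control fish at day 8 (p = 0.112, adjusted 0.336), and 59.3 ± 6.0 and 57.5 ± 5.8 M at day 14 (p = 0.477).

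The first comparison asked which genes differed between exposed and control fish 1 day after treatment. At day 8, 15 of 32 measured ribosome biogenesis genes fell in the exposed fish and none rose, in a list that passed its test at a preset correlation but not with an estimated one (adjusted p = 0.172 with an estimated correlation). The ribosome assembly factor urb2 fell by 1.85 ± 0.29 on the log2 scale (SE, adjusted p = 0.00178), from 6.69 ± 2.69 to 1.86 ± 0.83 CPM (counts scaled by library size; SD, n = 10). LOC106611136, an ornithine decarboxylase 1-like gene whose enzyme opens polyamine synthesis, fell by 1.77 ± 0.44 (adjusted p = 0.0318), from 13.7 ± 8.0 to 4.01 ± 2.15 CPM. Among the genes that rose, LOC106567948, similar to diacylglycerol O-acyltransferase 2, which completes triglyceride synthesis, increased by 2.20 ± 0.44 (adjusted p = 0.0127), from 21.2 ± 15.4 to 97.5 ± 86.0 CPM. LOC106611368, similar to type II iodothyronine deiodinase, which activates thyroid hormone, rose by 1.58 ± 0.38 (adjusted p = 0.0267), from 41.7 ± 23.9 to 125 ± 62.7 CPM. In each of these 4 genes all 10 exposed fish lay beyond the control median. Of 30397 genes tested, 142 rose and 352 fell with lufenuron at day 8 (edgeR quasi-likelihood test, false discovery rate of 0.05), so that 71.3% of the 494 genes fell (two-sided binomial p = 1.27e-21, across genes, which are not independent). With total counts as the only scaling 57 rose and 499 fell, a share of 89.7%. Among the 4884 genes with an unadjusted p under 0.05 in the main fit, 2646 fell, so the skew was smaller over this wider set.

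Among the other large falls, LOC106563191, an S-adenosylmethionine synthase that makes the methyl donor of the cell, fell by 1.69 ± 0.36 (adjusted p = 0.0133), from 7.20 ± 5.75 to 2.23 ± 0.94 CPM, and LOC106569427, similar to the arginine methyltransferase PRMT5, fell by 1.42 ± 0.30, from 11.8 ± 5.4 to 4.44 ± 1.59 CPM. Falls of 1.62 and 1.40 were found for LOC106583263, a yrdC domain gene, and LOC106572754, a serine tRNA ligase. LOC106560341, similar to 4-hydroxyphenylpyruvate dioxygenase, LOC106602585, similar to the splicing protein PRP19, LOC106568934, similar to retinol-binding protein 1, and LOC106613489, similar to protein phosphatase inhibitor 2, changed by -1.67, -1.42, -1.37 and -1.36. All 10 exposed fish lay below the control median for each of these 8 genes.

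The rises included several regulators. LOC106600841, similar to the transcription factor NRF1 (nuclear factor erythroid 2-related factor 1), which controls proteasome genes, rose by 1.53 ± 0.24 (adjusted p = 0.00178), from 8.59 ± 2.96 to 24.8 ± 4.92 CPM, with all 10 exposed fish above the control median. LOC106585360 (Krueppel-like factor 9) rose by 1.69 ± 0.43, from 1.32 ± 0.65 to 4.26 ± 4.51 CPM, and LOC106601915, similar to SOCS3, an inhibitor of cytokine signalling, by 1.605 ± 0.434 (adjusted p = 0.0352 and 0.0449). Other measured entries of Krueppel-like factor 9 were not called. LOC106584385, LOC106602470, LOC106598834 and LOC106568757 were at -0.59, -0.18, 0.27 and 0.060. LOC106589320, similar to the adaptor protein GRB7, and LOC106569990, similar to intermediate filament family orphan 1, rose by 1.38 and 1.37. LOC106578688, similar to the adhesion molecule CEACAM5, and LOC106587278, similar to skin secretory protein xP2, rose by 1.74 and 1.42; without exposed fish 3 the second value was 0.84. Among the genes named by size, which passed the filters on level and fish, the largest rise was 2.35 for LOC106566216 (ribosomal protein L32-like). It rested on exposed fish 5, at 19.6 CPM. Without that fish it was 0.67, with an adjusted p of 0.282.

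**Figure D2:**
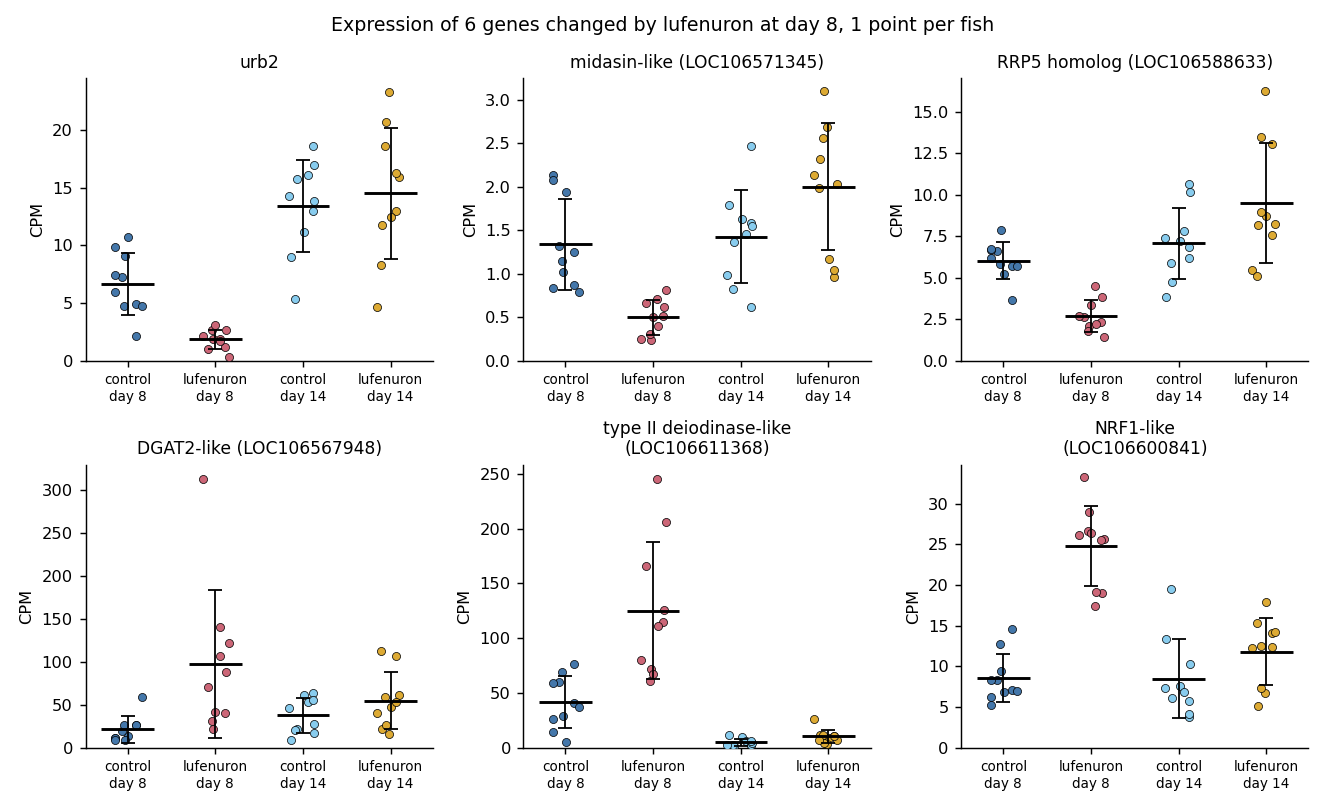
CPM of 6 genes in each of the 40 fish by group, 1 point per fish, with the group mean and SD as line and bar; each panel has its own linear axis. The mean values of urb2, LOC106571345 and LOC106588633 were lowest in the exposed fish of day 8, and those of LOC106567948, LOC106611368 and LOC106600841 were highest in them.

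The gene lists fixed in advance were tested with camera, which asks whether a list's genes move more than other genes, at a preset correlation between genes of 0.01. The ribosome biogenesis list fell at day 8: 15 of its 32 measured genes passed the test over all genes and all 15 fell, while 28 fell and 1 rose when adjusted over the list alone. Its median was -0.72 (adjusted p = 8.33e-28 over 30 lists; adjusted p = 0.172 with an estimated correlation). The members with the smallest p were polr1a, the large subunit of RNA polymerase I, which transcribes ribosomal RNA, at -1.10 ± 0.19 (9.35 ± 2.87 to 4.36 ± 1.45 CPM), the WD repeat 43-like genes LOC106610597 and LOC106561875 at -0.98 and -0.89, and nop56, a protein of the particles that methylate ribosomal RNA, at -0.82 ± 0.17 (109 ± 29.4 to 61.3 ± 12.2 CPM). In all 4, all 10 exposed fish were below the control median. The ribosomal proteins themselves did not pass, with a median of -0.0071 over 164 genes, a mean of 0.017 and 1 rise, the L32-like gene above (adjusted p = 0.656).

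Of 72 measured SUMO pathway genes, 4 fell and none rose over all genes, and 8 fell and 3 rose when adjusted over the list alone. The series title names this pathway, so these counts are not independent evidence of its direction. The list median was -0.13 (camera adjusted p = 0.00294; adjusted p = 0.524 with an estimated correlation). The 4 genes were LOC106602897, similar to SENP3, a protease that removes SUMO, at -1.01 ± 0.21 (adjusted p = 0.0133; 1.73 ± 0.51 to 0.856 ± 0.242 CPM), LOC106586530, similar to the SUMO ligase RanBP2, at -0.62 ± 0.15 (13.8 ± 3.1 to 8.99 ± 1.54 CPM), uspl1, a SUMO isopeptidase, at -0.56 ± 0.15, and LOC106598790, similar to SENP5, at -0.38 ± 0.10. The protease gene senp6 had a value of 0.51 ± 0.15 (adjusted p = 0.0579 over all genes). Values of the SUMO genes LOC106574529 (small ubiquitin-related modifier 3) and smo3b (modifier 3-A) were -0.58 and -0.50 and did not pass (adjusted p = 0.0898 and 0.102).

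**Figure D3:**
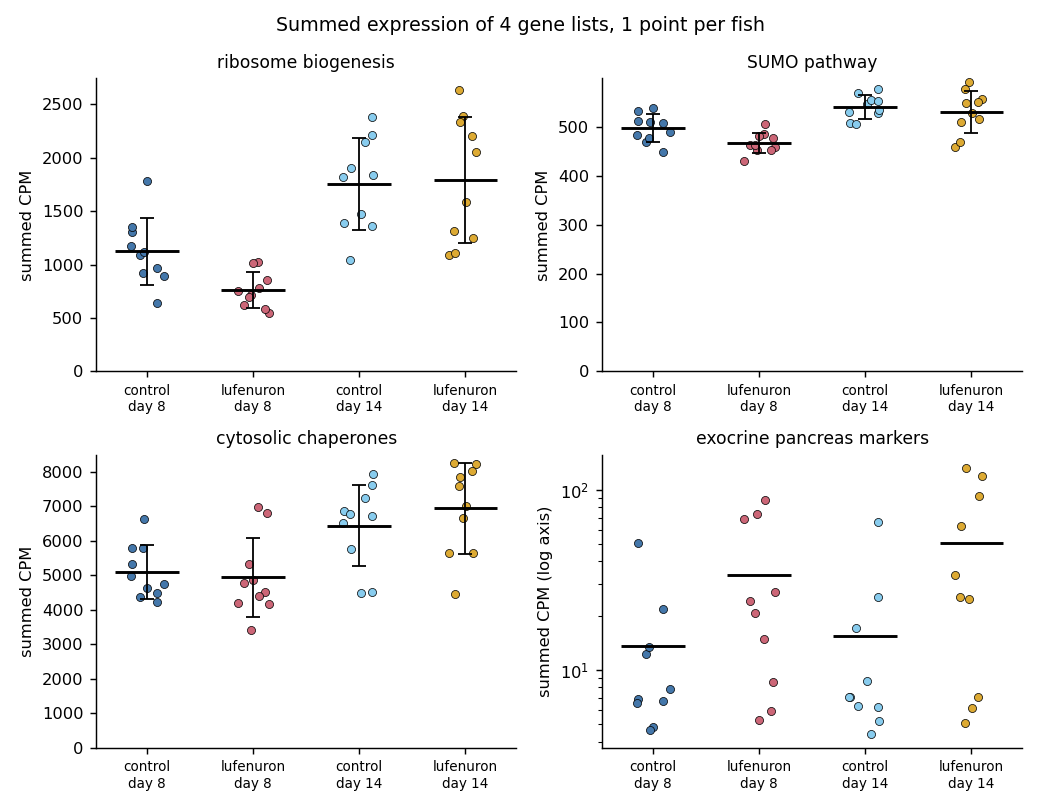
Summed CPM of the ribosome biogenesis, SUMO pathway, cytosolic chaperone and exocrine pancreas lists in each of the 40 fish by group, 1 point per fish; lines are group means and bars are SDs, and the pancreas panel has a log axis with means only. The mean sums of the ribosome biogenesis list were 1124 CPM in day 8 controls and 761 CPM in day 8 exposed fish, against 1757 and 1796 CPM at day 14.

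Another 5 lists moved downward at day 8 in the camera test with few or no single genes past the threshold. All 37 measured cell cycle genes had negative fold changes, with a median of -0.36 (adjusted p = 4.67e-04) and no gene called; mcm5, part of the helicase of DNA replication, was at -1.12 ± 0.41. The cytosolic chaperones had a median of -0.21 over 54 genes, 48 of them negative and 0 called, or 2 falls when adjusted over the list alone (adjusted p = 1.96e-05). For endoplasmic reticulum stress the median was -0.25 over 57 genes (adjusted p = 0.00115), with calreticulin-like LOC106599148 at -0.77 ± 0.23, and for the proteasome it was -0.12 over 79 genes (adjusted p = 0.0132), with no gene called in either list, also when adjusted over the list alone. The splicing factors had a median of -0.11 over 98 genes (adjusted p = 6.63e-04) and 1 fall, also when adjusted over the list alone, LOC106563120, a Sm D3 core protein, at -1.43 ± 0.37. The fall of LOC106563120 missed at least 1 filter, on level or on fish, for genes named by size. With an estimated correlation the adjusted p of these 5 lists lay between 0.586 and 0.801.

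Upward, 8 lists passed camera at day 8. All 12 measured exocrine pancreas markers had positive fold changes, with a median of 1.57 (adjusted p = 4.67e-04) and none called, also when adjusted over the list alone. Summed over the list, they made up 33.6 ± 30.9 CPM in exposed and 13.5 ± 14.0 CPM in control fish. The difference in the log2 sum did not pass a permutation test (unadjusted p = 0.0702), which was not among the tests fixed in advance. The xenobiotic oxidation list had a median of 0.14 over 45 genes (adjusted p = 0.0132) and 1 rise, also when adjusted over the list alone: LOC106612446, the reductase that passes electrons to cytochromes P450, at 0.79 ± 0.20 (113 ± 42 to 195 ± 69 CPM). The circadian clock list had a median of 0.13 over 64 genes (adjusted p = 0.029), with rises of cryptochrome-1-like LOC106565112 by 0.89 ± 0.20 and of LOC106607162, similar to thyrotroph embryonic factor, by 0.59 ± 0.15; when adjusted over the list alone 4 rose and 2 fell. Single rises were found in oxidative stress defence (median 0.096 over 48 genes, adjusted p = 0.00859; keap1-like LOC106564503 at 0.47), glucose metabolism (0.15 over 46 genes, adjusted p = 0.0226; LOC106587569, similar to glucose-6-phosphate isomerase, at 3.30) and acute phase and complement (0.13 over 68 genes, adjusted p = 0.0121; the SOCS3-like gene). The counts adjusted over the list alone were 1, 1 and 1 rises, with 1 fall in glucose metabolism. The rise of 3.30 for LOC106587569 missed at least 1 filter for genes named by size. These filters are a mean of 1 CPM and 8 of 10 exposed fish beyond the control median. Fatty acid oxidation (0.18 over 33 genes, adjusted p = 0.0218) and the stellate cell and endothelium markers (0.15 over 35 genes, adjusted p = 0.00693) had no gene called, also when adjusted over the list alone. All 8 lists had an adjusted p of 0.586 with an estimated correlation.

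The other 14 lists did not pass camera at day 8. Bile duct and gut epithelium markers had a median of 0.20 over 22 genes (adjusted p = 0.0991), with 4 rises when adjusted over the list alone, among them vil1 (villin, 2.96) and cdh17 (2.13), and none over all genes. Without exposed fish 3 these 2 values were 0.63 and 0.79, and no gene of the list passed when adjusted over the list alone. Lipogenesis had a median of 0.087 over 39 genes (adjusted p = 0.0591), with 1 rise, the diacylglycerol acyltransferase gene above, and 3 rises and 2 falls when adjusted over the list alone. The genes of chitin and hyaluronan turnover, the list nearest to the target of lufenuron in arthropods, had a median of 0.065 over 21 genes (adjusted p = 0.436), with no gene called and 1 rise when adjusted over the list alone. Its listed symbols chs1 (chitin synthase) and chit1 matched no gene, so neither was tested. The list summed to 1310 CPM in exposed fish 3, against a median of 429 CPM in the exposed fish of day 8. Transcription and chromatin had 1 fall of 100 genes, LOC106569448, similar to CHD8, at -0.33, and 2 when adjusted over the list alone (adjusted p = 0.318). No gene was called, by either adjustment, in cholesterol synthesis (median -0.064), erythrocyte markers (-0.024), the growth hormone and IGF axis (0.031), hepatocyte markers (0.066), interferon response (0.096), lymphocyte markers (-0.049), macrophage and neutrophil markers (-0.075), oestrogen response (0.32), p53 targets and apoptosis (0.014) or xenobiotic conjugation and export (0.091). Camera's adjusted p for these 10 lists was between 0.0991 and 0.883, and mean and median differed in sign for erythrocyte markers, for macrophage and neutrophil markers, and for p53 targets and apoptosis.

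With the DESeq2 test 1048 genes were called at day 8, of which 63.4% fell. Leaving out single fish moved the count by over 1.5 times in 9 cases: it was 1246 without control fish 1, and 128, 311, 168, 212 and 265 without control fish 3, 4, 5, 7 and 9, and 161, 220 and 236 without exposed fish 2, 4 and 6. Of the 20 genes named by size, 7 passed in all 40 such fits. Without the 9 fish whose pancreas markers summed to over 50 CPM, 34 genes were called at day 8, 16 that rose and 18 that fell, and with the log2 sum of these markers as a covariate 225; both alternatives were chosen after the data were seen.

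The second comparison asked which genes differed 7 days after treatment. No gene passed at day 14 in edgeR's quasi-likelihood test (smallest adjusted p = 0.117), while 2437 genes had an unadjusted p under 0.05, and DESeq2 called 20 genes, of which 19 fell. Without exposed fish 2 of day 14, edgeR called 1 gene. The genes with the smallest p are given as values. LOC106612162, similar to the apoptosis inhibitor XIAP, was at -0.45 ± 0.09 (SE), with 14.7 ± 1.8 CPM in controls and 10.8 ± 1.8 CPM in exposed fish (SD, n = 10). The secreted immune proteins LOC106570622 (CD5 antigen-like) and LOC106579598 (complement C1q-like 3) were at -1.37 ± 0.32 and -0.84 ± 0.20, with 1797 ± 1168 against 697 ± 324 CPM and 1331 ± 478 against 746 ± 261 CPM, and LOC106611899 (wolframin-like) and slc37a1 were at -1.31 and -0.45. On the higher side, LOC100194692 (Krueppel-like factor 11, a transcription factor) was at 1.12 ± 0.26, with 25.4 ± 7.7 CPM in controls and 55.1 ± 18.4 CPM in exposed fish. LOC106569900 (similar to acidic leucine-rich nuclear phosphoprotein 32 E), LOC106571371 (acid sphingomyelinase-like phosphodiesterase 3a), prs23 (serine protease 23) and LOC106566364 (nuclear transcription factor Y alpha-like) were at 0.65, 0.54, 0.48 and 0.35. Apart from the first, the adjusted p of these 10 genes was 0.396, and at least 9 of 10 exposed fish lay on the same side of the control median.

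Among the gene lists at day 14, 5 passed camera downward. The acute phase and complement list had a median of -0.31 over 68 genes, 56 of them negative (adjusted p = 1.33e-11), with LOC106560550, similar to complement factor H, at -0.45 ± 0.12. Hepatocyte markers had a median of -0.064 over 22 genes and did not pass (adjusted p = 0.0982). No gene of that list was called over all genes and 3 fell when adjusted over the list alone, among them LOC106608112, an alpha-1-antitrypsin homolog, at -0.47 ± 0.15. Their summed level was 115486 ± 18294 CPM in exposed and 139296 ± 22991 CPM in control fish (SD, n = 10, permutation p = 0.0177, a test chosen after the data were seen). At day 8 it was 133611 ± 24796 and 128982 ± 16702 CPM (permutation p = 0.625). These sums use TMM scaling, whose mean factor at day 14 was 1.09 in exposed and 0.963 in control fish, so the day 14 gap depends in part on it. With total counts as the only scaling the median of the hepatocyte markers turned to 0.11, and was -0.079 relative to the median of all genes. Cholesterol synthesis had a median of -0.28, with 35 of 38 genes negative (adjusted p = 1.09e-11) and insig1, a sensor of sterol levels, at -0.50 ± 0.16. Ribosomal proteins had a median of -0.19, with 154 of 164 genes negative (adjusted p = 4.82e-30), endoplasmic reticulum stress -0.21 over 57 genes (adjusted p = 0.00106) and the proteasome -0.13 over 79 genes (adjusted p = 1.81e-05). Upward, the exocrine pancreas markers had a median of 2.02 over 12 genes and the stellate cell and endothelium markers 0.24 over 35 genes (both adjusted p = 1.34e-04), the growth hormone and IGF axis 0.15 over 41 genes (adjusted p = 0.00592) and the cytosolic chaperones 0.058 over 54 genes (adjusted p = 0.0228). With an estimated correlation none of the 9 lists passed, with adjusted p between 0.476 and 0.757. No member of them was called over all genes; adjusted over the list alone, 1 chaperone rose and 1 ribosomal protein fell. Pancreas markers summed to 50.7 ± 47.9 CPM in exposed and 15.4 ± 19.2 CPM in control fish. The log2 sums had an unadjusted permutation p of 0.0388, in a test not among those fixed in advance. The ribosome biogenesis and SUMO lists had medians of 0.031 and -0.027 (adjusted p = 0.701 and 0.597). Scaling by total counts alone moved the median of all genes by 0.18 at day 14, and the proteasome median turned to 0.041, while relative to that shift no called list changed sign. The 10 most abundant genes took 19.9% ± 1.4 of the reads in exposed and 22.6% ± 1.5 in control fish at day 14 (SD, n = 10, permutation p = 7e-04, a test chosen after the data were seen).

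The third comparison tested whether the effect of lufenuron differed between the days, as the difference of the 2 log2 fold changes. The ribosome assembly genes urb2, LOC106571345 (midasin-like) and LOC106588633 (similar to RRP5, which processes ribosomal RNA) had differences of 1.96 ± 0.39, 1.89 ± 0.36 and 1.59 ± 0.28 (SE), with fold changes of -1.85, -1.40 and -1.16 at day 8 and 0.11, 0.49 and 0.42 at day 14. LOC100194692 (Krueppel-like factor 11) went from -0.69 to 1.12 and ccr9, a chemokine receptor, from -2.63 to 2.91. Levels of ccr9 were 3.28 ± 5.33 CPM in day 8 controls and 2.99 ± 5.44 CPM in day 14 exposed fish, with SDs above the means. In day 8 exposed fish and day 14 controls they were 0.531 ± 0.269 and 0.396 ± 0.224 CPM. In the other direction were hdac6, a deacetylase of tubulin, at -1.64 ± 0.31, its relative LOC106572926 at -1.55 ± 0.30, LOC106600502 (ski-like) at -1.53 ± 0.31 and s41a2 at -0.63; fold changes of hdac6 were 0.84 at day 8 and -0.80 at day 14. These are 9 of the 15 genes whose effect differed (8 upward and 7 downward, smallest adjusted p = 0.0394; 3277 genes at an unadjusted p under 0.05). In addition polr1a differed by 1.30 ± 0.26 (adjusted p = 0.0478), the only ribosome biogenesis gene called over all genes, while 22 of the 32 passed upward when adjusted over the list alone.

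Of the lists, ribosome biogenesis differed between days with a median of 0.72 (camera adjusted p = 2.60e-20) and cytosolic chaperones with 0.31 (adjusted p = 6.78e-08). Acute phase and complement (-0.43, adjusted p = 1.31e-11), cholesterol synthesis (-0.29, adjusted p = 1.49e-04), lipogenesis (-0.23, adjusted p = 0.00741), ribosomal proteins (-0.20, adjusted p = 3.62e-15) and oxidative stress defence (-0.093, adjusted p = 0.0323) differed downward. With an estimated correlation none of these 7 lists passed, with adjusted p between 0.255 and 0.758, and among these lists, besides ribosome biogenesis, 2 chaperones passed when adjusted over the list alone. The SUMO list did not pass, with a median of 0.099 and 2 genes upward when adjusted over the list alone (adjusted p = 0.0660). Scaling by total counts alone moved the median of all genes by 0.25 for this contrast, which turned the medians of lipogenesis, oxidative stress defence and ribosomal proteins positive, although none of the 7 changed sign relative to that shift.

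DESeq2 called 133 genes in place of the 15, total counts as the only scaling 422 (411 upward and 11 downward), no filter on low counts 3, body weight as a covariate 4, and the fit without the 3 day 14 controls under 20 g 5. Removal of 1 fish moved the count by over 1.5 times for 34 of the 40 fish. It was 0 without day 8 control fish 2, 3, 5 or 9, day 8 exposed fish 9, day 14 control fish 2, 3, 4 or 5, or day 14 exposed fish 4 or 7. It was 8, 5, 6, 2 and 2 without day 8 control fish 4, 6, 7, 8 and 10, and 9, 5, 6, 4, 5 and 4 without day 8 exposed fish 1, 2, 3, 4, 6 and 7. It was 4, 5, 6 and 6 without day 14 control fish 1, 6, 7 and 10, and 2, 2, 3, 6 and 6 without day 14 exposed fish 3, 5, 6, 8 and 10. It was 104, 74 and 48 without day 8 control fish 1, day 14 exposed fish 2 and day 14 control fish 9. Of the 9 genes named for the difference, 0 passed in all 40 such fits, and ccr9 passed in 5. Without the fish with pancreas markers over 50 CPM no gene was called, and with the markers as a covariate 1.

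Among the day 8 genes as a set, the 352 that fell had a median of -0.77 at day 8 and 0.030 at day 14, where 208 of them were positive, and the 142 that rose had medians of 0.69 and 0.027. Across all 30397 genes, which are not independent replicates, the fold changes of the 2 days correlated with r = 0.15 (95% jackknife interval over fish -0.17 to 0.47). No gene was called at both days, since none was called at day 14 by edgeR.

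The last comparisons asked how the liver changed from day 8 to day 14 without exposure and with it. Each day had its own fish. A change with time therefore cannot be told apart from differences in feeding, time of day, handling or library preparation between the sampling days. In controls, hepc1 (hepcidin, the hormone that limits iron release) rose by 5.13 ± 1.00 (SE), from 10.8 ± 13.9 to 379 ± 290 CPM, and the second hepcidin gene LOC106584587 by 3.97 ± 1.06. The heat shock gene hs90a rose by 4.73 ± 0.79, LOC106601018 (HSP70-like) from 0.580 ± 0.456 to 10.8 ± 17.7 CPM, and LOC106611136, the ornithine decarboxylase-like gene, by 2.73 ± 0.45, from 13.7 ± 8.0 to 90.3 ± 55.4 CPM; without day 14 control fish 8, hs90a rose by 3.11. LOC106592479 (similar to DDIT4, which restrains growth signalling through mTOR) fell by 4.06 ± 0.51, from 8.96 ± 4.91 to 0.528 ± 0.712 CPM, and LOC106611368, the deiodinase-like gene, by 3.08 ± 0.41, from 41.7 ± 23.9 to 4.92 ± 3.31 CPM. LOC106566297 (translation initiation factor IF-2-like), LOC106565446 (25-hydroxyvitamin D 1-alpha hydroxylase, which activates vitamin D) and ccr9 changed by -3.45, -3.25 and -3.05. The adjusted p of these 10 genes ran from 1.00e-08 to 0.00789, and 5877 of 30397 genes changed in controls, 3150 up and 2727 down, or 1957 up and 3051 down with total counts as the only scaling.

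In exposed fish 10609 genes changed, 5374 up and 5235 down, or 7917 up and 2548 down with total counts as the only scaling, which moved the median of all genes by 0.19. LOC106601018, hs90a and LOC106611136 rose by 4.84 ± 0.68, 4.68 ± 0.79 and 4.202 ± 0.486, the last from 4.01 ± 2.15 to 73.8 ± 32.5 CPM, and LOC106584850, similar to the co-chaperone DNAJA4, by 4.12 ± 0.40. LOC106592479 fell by 5.10 ± 0.55. The values of the other 5 genes named by size depended on single fish. Without day 14 exposed fish 4, at 33.0 CPM, the keratin gene LOC106566974 dropped from 4.07 to 0.99 and was no longer called. Without day 8 exposed fish 3, cndp1, LOC106577892 (mucin-17-like), LOC106603448 (a potassium channel) and LOC106572521 (bridging integrator 2-like) went from -4.40, -4.34, -4.51 and -4.35 to -1.36, -2.45, -2.39 and -2.53. Both time comparisons together held 4574 genes changed in the same direction, 2468 upward and 2106 downward, where independent lists would share 557 and 470. Leaving out the fish with pancreas markers over 50 CPM gave 6608 genes in exposed fish.

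Lists were tested over time only after the data had been seen. Cytosolic chaperones rose in both, with 41 of 54 genes up and 1 down in controls (median 0.75, camera adjusted p = 1.18e-20) and 45 up and 2 down in exposed fish (median 1.10, adjusted p = 9.59e-26); with an estimated correlation the adjusted p was 0.0819 in controls and 0.0329 in exposed fish. Ribosome biogenesis rose with 20 and 29 of 32 genes, beside 1 fall in each (medians 0.60 and 1.37; adjusted p = 0.513 and 0.116 with an estimated correlation), nop56 by 0.87 ± 0.17 in controls and 1.63 ± 0.17 in exposed fish. Endoplasmic reticulum stress rose with 20 and 28 of 57 genes, beside 0 and 2 falls, and cholesterol synthesis passed in controls, with 19 rises and 3 falls of 38 and idi1 at 1.11 ± 0.23. In exposed fish it had 12 rises and 3 falls and did not pass (medians 0.49 and 0.24). Cell cycle genes fell, 17 of 37 in controls and 16 in exposed fish, the latter beside 8 that rose. The cyclin B1 gene ccnb1 was at -2.68 ± 0.34 and -2.33 ± 0.34. In the growth hormone and IGF axis 14 of 41 fell in each, beside 1 and 2 rises, among them the insulin-like growth factor I gene LOC106609475 at -1.70 ± 0.33 in controls. The circadian clock list fell with 18 and 24 of 64 genes, beside 8 and 8 that rose, with LOC106607162 at -1.36 and -1.77. Erythrocyte markers rose with 12 and 19 of 37 genes, beside 1 and 2 falls (medians 0.60 and 0.71, adjusted p = 1.30e-04 and 0.00445), with gata1, a transcription factor of red cells, at 0.89 ± 0.19 and 0.93 ± 0.19. Stellate cell and endothelium markers passed downward in controls, with 6 falls and 1 rise of 35 (median -0.25, adjusted p = 0.00514). In exposed fish they had 10 falls and 2 rises and did not pass (median -0.38, adjusted p = 0.0696), and the difference did not pass (adjusted p = 0.857). Acute phase and complement passed in opposite directions, with 4 rises and 1 fall of 68 in controls (median 0.19, adjusted p = 0.0314) and 1 rise and 14 falls in exposed fish (median -0.32, adjusted p = 0.0417). The gene c9 (complement component 9) fell by 0.65 ± 0.17 in exposed fish. Splicing factors passed upward in both, with 25 rises and 5 falls of 98 in controls and 40 and 7 in exposed fish. The proteasome passed upward in controls, with 5 rises and 1 fall of 79 (median 0.21), and did not pass in exposed fish, with 13 and 1 (median 0.19, adjusted p = 0.0696), nor for the difference (adjusted p = 0.563). Lipogenesis (8 rises and 3 falls of 39) and ribosomal proteins (18 and 0 of 164) passed upward in controls. In exposed fish they had 8 and 6, and 5 and 6, and did not pass. Their differences and those of cholesterol synthesis and of acute phase and complement are the ones given in the third comparison, where they passed at the preset correlation and not with an estimated one. The SUMO list passed in exposed fish, with 29 rises and 14 falls of 72 (adjusted p = 0.0125), and did not pass in controls, with 17 and 8 (adjusted p = 0.0853). The difference of these 2 results is the third comparison, where the list did not pass. With an estimated correlation the adjusted p of the lists that passed, other than the chaperones, was between 0.116 and 0.848.

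The genes that fell with lufenuron at day 8 were mostly genes that rose with time in controls. Of the 352, 327 were positive from day 8 to day 14 in controls and 214 were called upward, where independent lists would share 36.5, and 3 were called downward. Of the 142 that rose, 30 were called downward in controls, against 12.7 for independent lists, and 11 upward. Both contrasts subtract the day 8 controls, which by itself gives a positive correlation: unchanged groups simulated against the same controls gave a correlation across genes of 0.49 and a covariance of 0.045, and the observed values were -0.19 and -0.042. With the day 8 controls split at random into 2 equal parts, 1 for each contrast, the mean correlation over 10 splits was -0.30 (range -0.36 to -0.20) and the mean covariance was -0.082 (range -0.107 to -0.048).

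**Figure D4:**
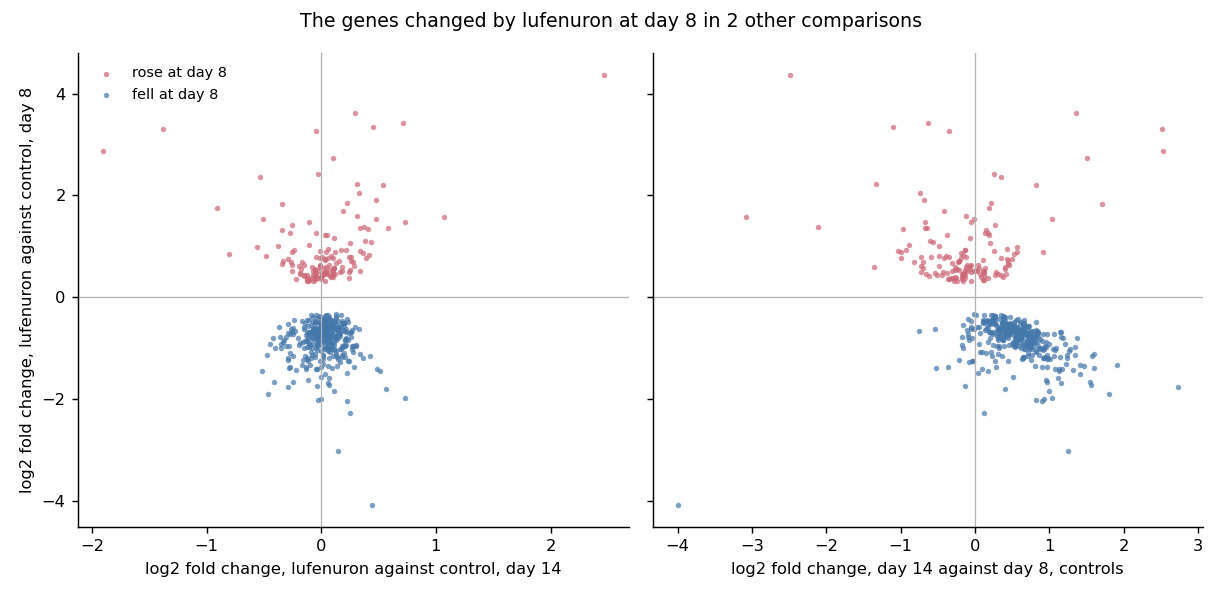
Log2 fold changes of the 494 genes called at day 8, with lufenuron at day 8 on the vertical axis and, on the horizontal axis, lufenuron at day 14 (left panel) or the change from day 8 to day 14 in controls (right panel), 1 point per gene. Of the 352 genes that fell at day 8, 208 have a positive value on the horizontal axis of the left panel and 327 on that of the right panel.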

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

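Of the tests below, the splits of the fish for the day 8 count, the exchange of labels, the thinning and the pancreas covariate were chosen only after the result was seen.

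A first pattern is that 352 of the 494 genes changed by lufenuron at day 8 fell, beside 2646 of 4884 at an unadjusted p under 0.05. Chance alone was unlikely for the count of 494, since 1 of 100 splits of the fish, the real one, gave as many genes. The highest other split gave 21. These splits scored the count and not the share that fell, and the count ran from 128 to 1246 with 1 fish left out. Fewer reads in the exposed fish do not account for this pattern: with every library thinned to the smallest total, 507 genes were called and 73.8% of them fell. Exocrine pancreas tissue in the liver pieces does not account for the falls as a trend either, since the genes that fell kept 97.4% of their median, -0.75 against -0.77, with the pancreas markers as a covariate, where 151 of 225 calls fell (67.1%). Without the 9 fish with high pancreas markers these genes had a median of -0.78, but 18 of 34 calls fell (52.9%), so that more falls than rises among the calls were not shown without those fish. Differences between tanks, feeding or handling stay open beside an effect of lufenuron that may have lowered these genes.

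A second pattern is that 1 control fish of day 8 sat with the exposed fish. On a scale where 0 is the mean of the other controls and 1 that of the other exposed fish, over about 500 genes chosen without it, control fish 1 scored 1.14, while the other controls reached 0.421 and the exposed fish 0.721 ± 0.273 (SD, n = 10). An exchange of labels needs an exposed fish among the controls, and the lowest exposed fish scored 0.313, between the groups, so that this cannot be told apart from spread between fish. Low depth is argued against: its total of 49.4 M reads ranked 3 from the lowest among the 10 day 8 controls, the 2 shallower ones, fish 8 and 10, scored 0.135 and 0.363, and with every library thinned to the smallest total fish 1 scored 1.15 and the highest other control 0.416. A single wrong label or a control fish with a similar liver state may also explain it, and without this fish 1246 genes were called at day 8.

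Another pattern is that edgeR called no gene with lufenuron at day 14 although 2437 genes had an unadjusted p under 0.05 and DESeq2 called 20. All 100 of the 100 splits of the fish gave at least 0 genes, which says nothing against chance. Another split gave 1418 genes, and what set its groups apart was not tested. A wider spread that hides an effect of the same size was asked about over the genes of day 8. The ratio of their median fold change at day 14 to that at day 8 was -0.023 (95% jackknife interval over fish -0.317 to 0.271). These genes were called by their day 8 values in the same fish. That choice tends to enlarge those values, which pulls the ratio toward 0, and favours genes with a small spread at day 8. The ratio therefore argues against an effect as large as the one measured at day 8, and not against a smaller one. Over these genes the median SD of log2 CPM was 0.371 in control and 0.426 in exposed fish at day 14, against 0.435 and 0.356 at day 8. Over all tested genes it was wider at day 14, at 0.444 in control and 0.414 in exposed fish, against 0.392 and 0.391 at day 8. Whether other genes changed at day 14 by less than this design detects stays open.

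Of 143 groups of 10 fish tested for a fish far from the other 9, 17 had one, and about 1 in 20, or 7.15, does so by chance. Day 8 control fish 1 was far below the other controls for urb2 (2.12 CPM), LOC106611136 (1.25 CPM), LOC106583263 (0.276 CPM), LOC106602585 (0.254 CPM), LOC106569427 (1.59 CPM), LOC106572754 (1.27 CPM) and LOC106601018 (0.0212 CPM). Day 14 exposed fish 2 stood apart for hdac6 (4.77 CPM), LOC106600502 (5.13 CPM) and LOC106611136 (9.01 CPM). LOC106566216 was at 19.6 CPM in day 8 exposed fish 5 and 0.103 CPM in day 8 control fish 10. Other fish far from their group were day 8 exposed fish 8 in body weight (44 g), day 8 exposed fish 4 for LOC106583263 (0.0762 CPM), day 8 control fish 7 for hdac6 (5.54 CPM), day 14 control fish 2 for LOC106612162 (19.1 CPM) and day 14 exposed fish 4 for LOC106566974 (33.0 CPM).

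The effect of lufenuron differed between the days for 15 genes by the test of the difference itself, a count that 1 of 100 splits, the real one, reached, with 1 gene in the highest other. The splits exchanged exposure within each day, so they stand for no effect at either day and not for an equal effect at both. With 1 fish left out the count ran from 0 to 104, and it moved by over 1.5 times for 34 of the 40 fish. Among the 15 genes were ccr9 (5.53), urb2 (1.96), LOC106571345 (1.89), LOC100194692 (1.80), LOC106588633 (1.59), hdac6 (-1.64), LOC106572926 (-1.55), LOC106600502 (-1.53) and s41a2 (-0.63). Lists whose effect differed in camera at a preset correlation had median differences of 0.72 for ribosome biogenesis, 0.31 for cytosolic chaperones, -0.43 for acute phase and complement, -0.29 for cholesterol synthesis, -0.23 for lipogenesis, -0.20 for ribosomal proteins and -0.093 for oxidative stress defence. None of these 7 lists passed with an estimated correlation (adjusted p between 0.255 and 0.758), and the last 3 medians turned positive with total counts as the only scaling.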

How the results depend on the processing

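The settings on pancreas markers and the thinning were chosen after the data were seen. At day 8, counts of 402 to 556 genes came from RLE scaling, total counts, no filter, only the groups compared, body weight, non-robust quasi-likelihood and thinning. DESeq2 gave 1048, the pancreas covariate 225, and the fit without the 9 fish with high pancreas markers 34; random removals of as many fish per group gave a median of 9.5 (0 to 1445), with 14 of 20 as low, so fewer fish suffice for that drop. At day 14 DESeq2 gave 20 and each of the other settings 0. The difference count of 15 went to 422 with total counts, 133 with DESeq2, 3 without a filter, 4 with body weight, 5 without the light controls, 1 with the pancreas covariate and 0 without the pancreas fish. In exposed fish over time 6608 genes were called without the pancreas fish. Apart from the smaller fits the cause was not tested. Leaving out 1 fish gave 128 to 1246 genes at day 8, 0 to 1 at day 14, 0 to 104 for the difference, 4738 to 6928 over time in controls and 9644 to 11345 in exposed fish. Body weight at day 14 reversed to -3.19 g without the light controls, whose removal is the cause.

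Of the lists past camera, 15 at day 8, 9 at day 14 and 7 for the difference, an estimated correlation left 0, 0 and 0 and fry 2, 0 and 0. Of 59 named results none reversed; those no longer past the threshold numbered 0 with RLE, 3 with total counts, 4 with DESeq2 (2 others newly passed), 11 without a filter, 6 with body weight, 0 with non-robust quasi-likelihood, 1 with thinning, 16 with the pancreas covariate and 31 without the pancreas fish, and 8 of 47 with only the groups compared and 5 of 39 without the light controls. The replicate number as a block gave 231 genes at day 8 and 8 for the difference, and moved no other count of genes by over 1.5 times; 17 of the 59 named results were then no longer past the threshold, among them 12 of the 20 genes named at day 8; the numbers mark different fish, 11 of 60 same-numbered pairs correlated over 0.1 (median -0.012), and 7 of 40 fish were closest to their own number. Unequal depth between fish mattered little for the day 8 count, since thinning gave 507 genes. Whether more reads would add genes was not tested.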

Other observations

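Of the tests below, the fasting, glucocorticoid and list split tests were chosen only after the result was seen, as were the 9 gene families, which were picked after the day 8 genes had been seen and so describe them.

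Genes that process ribosomal RNA were among those that fell at day 8. Of 58 measured genes of the small subunit processome and of nucleolar RNA proteins, 4 of which are also in the ribosome biogenesis list, 28 fell and none rose, where 0.672 falls would come from a random draw, and 57 were negative, with a median of -0.61. Examples are LOC106580531 (IMP4-like, -0.61 ± 0.12), LOC106586141 (WD repeat 75-like, -0.91 ± 0.18), rrp9 (-0.93 ± 0.19) and heatr1 (-1.14 ± 0.23), the last from 13.9 to 6.30 CPM. The family's median was 0.039 with lufenuron at day 14 and 0.55 over time in controls, where 40 of the 58 rose.

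Of 32 transfer RNA modifying enzymes 9 fell, where 0.371 would come from a random draw (median -0.41), among them trmt2b (-0.92 ± 0.18) and pus3 (-0.58 ± 0.13), and of 67 aminoacyl transfer RNA ligases 7 fell, where 0.776 would (median -0.29), among them yars2 (-0.72 ± 0.18) and mars (-0.84 ± 0.22). The median difference of the ligases in log2 CPM, 0.280, was reached by 7 of 100 splits of the fish (highest other 0.423), and that of the modifying enzymes, 0.396, by the real split alone (highest other 0.369). RNA polymerase I and III subunits had 5 falls of 32 (0.371 by a random draw) and RNA polymerase II subunits 2 of 19 (0.220), and their medians were reached by 6 and 5 of 100 splits. In mitochondrial import 3 of 41 fell (0.475 by a random draw, 4 of 100 splits), with LOC106580763 (TIM50-like) at -0.96 ± 0.20. There were 3 falls of 106 mitochondrial ribosomal proteins and 3 of 116 translation initiation factors, if2a at -1.04 ± 0.21 among the latter. A random draw would give 1.23 and 1.34, and the excess did not pass (Fisher's exact test, adjusted over the 9 families, p = 0.161 and 0.171). In these families 88 and 84 genes were negative, with medians of -0.16 and -0.096 that were reached by 5 and 19 of 100 splits. Complex I subunits of the respiratory chain had 0 falls and 0 rises of 41 by edgeR and a median of 0.0082.

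Day 8 exposed fish 3 had high levels of some genes, chosen after their values were seen, among them vil1 and cdh17 of the bile duct and gut epithelium list. Whether these transcripts came from gut, bile duct or another source was not tested. This fish had 89.9 CPM of vil1, 77.4 CPM of cdh17, 47.3 CPM of cndp1, 19.8 CPM of LOC106577892 (mucin-17-like) and 864 CPM of LOC106567267 (acidic mammalian chitinase-like). The next fish, day 8 exposed fish 10, had 9.78, 18.4, 2.61, 4.06 and 111 CPM of these genes. Both fish were also among the 9 with pancreas markers over 50 CPM, at 73.4 and 69.0 CPM.

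At day 14 the 20 genes called by DESeq2 included secreted proteins of the liver, which edgeR did not call and which are named here after their values were seen. Besides the CD5 antigen-like and C1q-like genes, LOC106571174 (leucine-rich alpha-2-glycoprotein-like) was at -1.14, LOC106592311 (complement factor I-like) at -0.63, LOC106572045 (properdin-like) at -0.56 and LOC100136573 (apolipoprotein A-I) at -0.33. The only rise was gbp (GSK-3-binding protein), at 1.03, from 24.0 to 48.8 CPM.

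One hypothesis was that the day 8 change lies along a main axis of variation between fish that exists without lufenuron at day 8. The day 8 fold changes correlated with the loadings of the first component of the day 14 fish within their groups with an absolute r of 0.429 across 5000 genes, which 2 of 100 splits of the day 8 fish reached (highest other 0.445, median 0.135). This is consistent with exposed fish having moved along an axis on which fish of the same group also differ at day 14. The day 14 fish include exposed ones, so an axis among untreated fish alone was not tested, and the correlation does not say what moves fish along it.

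Lower feed intake of the exposed fish may also be asked about. Each gene's log2 CPM was centred and divided by its SD over the day 8 fish, and a fish's score was the mean over the list. The SD given here is thus that of single genes, and not the spread of the score between fish. The score of fasting-induced genes differed by 0.0151 SD between exposed and control fish at day 8 (95% interval -0.195 to 0.226, permutation p = 0.882), with 6 of 10 exposed fish above the control median, and 0 of 46 genes called by edgeR. A glucocorticoid response gave a difference of 0.290 SD (95% interval -0.0843 to 0.664, permutation p = 0.120), with 9 of 10 exposed fish above the control median and 2 of 42 genes that rose, LOC106565346 (FKBP5-like, 0.70 ± 0.17) and LOC106585360 (Krueppel-like factor 9). The second FKBP5 gene, fkbp5, was at 0.60 and the other Krueppel-like factor 9 entries were between -0.59 and 0.27, and none of these was called. Both intervals reach beyond 0.2 SD, so neither hypothesis is decided.

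The number of lists past camera says little alone. As many lists as the 15 at day 8 came from 14 of 100 splits of the fish (highest other 19), as many as the 9 at day 14 from 71 (highest other 17), and as many as the 7 for the difference from 85 (highest other 18), so chance is not excluded for these counts. For single lists at day 8, 1 of 100 splits, the real one, gave a median as far from 0 for ribosome biogenesis (highest other 0.49 against 0.72), for SUMO (highest other 0.128 against 0.131) and for oestrogen response (highest other 0.311 against 0.320), which did not pass camera, 2 for fatty acid oxidation and for splicing factors, 4 for cytosolic chaperones, 6 for glucose metabolism, 9 each for the cell cycle, the circadian clock, oxidative stress defence and xenobiotic oxidation, and 13 for exocrine pancreas markers. As far from 0 or farther were 21 splits for endoplasmic reticulum stress, 22 for the proteasome, 24 for stellate cell and endothelium markers and 32 for acute phase and complement. Of the 9 lists past camera at day 14, acute phase and complement was reached by the real split alone (highest other 0.311 against 0.314), cholesterol synthesis by 3, ribosomal proteins by 4, exocrine pancreas markers by 7, and stellate cell and endothelium markers by 8. The others were reached by more splits, the growth hormone and IGF axis by 36, the proteasome by 37, endoplasmic reticulum stress by 40 and cytosolic chaperones by 63. For the difference the numbers were 2 for cytosolic chaperones, 3 for ribosome biogenesis (highest other 0.736 against 0.725) and for acute phase and complement, 7 for lipogenesis, 10 for ribosomal proteins, 13 for cholesterol synthesis and 31 for oxidative stress defence. Each comparison had 30 lists, and these shares are not adjusted for that number. The counts over time were reached by 1 of 100 splits each, the real one, with 107 genes in the highest other in controls and 5191 in exposed fish.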
